A study of Mus musculus with 6 samples.

How the data were processed

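Total RNA from 6 samples of Dgcr8-deficient mouse ESCs was biotin-labelled and measured on single-colour expression arrays, per the labels' protocols. The deposited table holds 33649 rows, each a set of probes, and 1 column per sample, and 0 columns were left without a sample. The authors processed the arrays with RMA, per the submitters' processing notes. RMA corrects background, normalizes quantiles between arrays and summarises probes. Its version, the software and the genome build are not given in the sources used here. The deposited values are taken as log2 expression: the log base is not stated, and base 2 is what RMA gives. They carry 2 decimals, and their medians lie between 5.60 and 5.62 on all 6 arrays. Because RMA makes the distributions of the arrays alike, a shift of all genes together cannot be seen in these values. Detection calls and scanner intensities were not used here, so a low level cannot be told from background.

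Groups and replicate numbers were taken from the sample titles and hairpin labels: 3 control hairpin and 3 miR-302 samples. The series' design text calls the samples of a group independent biological samples. No batch, slide or scan date was used here.

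Rows were named through the platform annotation. It lists a single gene for 23521 rows, several genes for 1814, and none for 8314. Rows with a single gene were kept, and of several rows of a gene (1082 genes) the row with the highest mean over the 6 arrays stood for it, which left 22180 genes. Of these, 21994 had their Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which was used for names and for which genes lie within each other. No coordinates are printed, since the build of the deposited table is not given.

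Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust prior, two-sided) on the deposited values, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Fold changes are differences of group means, and SE is limma's moderated standard error. Adjusted p-values printed for genes come from this fit. In all, 27 gene lists with 446 distinct genes, 406 of them measured, were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, which called 5 lists higher and 5 lower, and 0 lists with an estimated correlation, where 5 had an unadjusted p under 0.05. Limma's fry, which tests whether the genes of a list move 1 way on balance and compares them with no other genes, called 14.

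The genes named are the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, up to 4 members of each list with the smallest p, and Dgcr8, Trp53, Cdkn1a, Mdm2, Lats2, Rbl2, Larp7 and the miR-302 and miR-290 cluster genes. Provisional gene models were passed over for naming. Of the 122 genes named by this rule, 101 were called, and 64 of these were called in every fit that left out 1 array, while 37 lost their call in at least 1. Trp53 has no row with a single gene and was not analysed here.

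The alternatives were the replicate number as a block, leaving out each array in turn, only genes at or above the median level, an intensity trend with a robust prior, centring each array on its median, quantile normalization, the mean of all rows of a gene, every row on its own, array weights, an unmoderated test per gene, and a fold change of at least 1.5. A planned test of miR-302 seed matches in 3′ UTRs was not run, as no 3′ UTR sequences were used here. After the data were examined, 3 further lists were set up to test hypotheses of the closing section.

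The fit was tested on simulated data made from the control and miR-302 arrays' levels and spread over 22180 genes, for the comparison of miR-302 with control hairpin. Of 70, 64 and 66 genes changed 1.5-fold, 2-fold and 4-fold, 32.9%, 75.0% and 100% were recovered, and 8 of 145 calls were false. Far fewer genes were changed here than were called in the data. In the simulated lists, camera called none of 26 unshifted lists with either correlation, and fry called 2. Simulated genes were drawn independently of each other, so these lists cannot show whether the preset correlation of 0.01 is too low. The shifted list had a camera adjusted p of 3.54e-27 at the preset and 0.00742 with an estimated correlation, although its genes were independent. In the data, the estimated correlation ranged from −0.04 for let-7 targets to 0.95 for the epithelial list. It was −0.017 for the stress response list, −0.022 for G1 and S phase and −0.011 for interferon response, below the preset. These lists still lost their call, so a lost call does not by itself show correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.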

Results

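Gene expression was measured in mouse embryonic stem cells (ESCs) that lack Dgcr8, the RNA-binding partner of the Drosha nuclease. Without Dgcr8, primary miRNA transcripts are not cut and canonical miRNAs are not made. The 6 arrays form 2 groups. In 3 samples the cells carried a control hairpin, and in 3 they expressed miR-302, a miRNA family abundant in pluripotent cells, from a hairpin construct. The labels describe the samples of each group as independent biological samples. Values are log2 expression levels, and 22180 genes were tested. The small number of arrays limits the precision of every value.

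The comparison asks how expression of miR-302 in cells without other canonical miRNAs changes their transcripts, including those activated by p53, the subject of the series title. With miR-302, 3643 genes changed, of which 1592 were higher and 2051 lower (limma, adjusted p under 0.05). A change of at least 2-fold was reached by 260 of the higher and 254 of the lower genes. Without miR-302 replicate 1 these were 402 and 350, and without any 1 of the other arrays 186 to 203 and 217 to 239. The lower genes included the Nodal antagonists Lefty1 and Lefty2, the cyclin gene Ccnd2 and the apoptotic caspase gene Casp8, all reported targets of miR-302 or of miRNAs with its seed. The higher genes included keratin genes Krt8 and Krt18, trophectoderm transcription factor genes such as Gata3 and Eomes, and imprinted genes such as Peg10 and Igf2. Of 17 interferon response genes 8 were lower, and of 16 genes of the integrated and endoplasmic reticulum (ER) stress responses 9 were. Of 35 p53 target genes 14 were higher and 3 lower. Without any 1 array other than miR-302 replicate 1, only 4 to 6 of them were higher. The p53 list as a whole was not called by camera. Of 27 gene lists, camera at a preset correlation called 10, and with an estimated correlation it called 0. The estimated setting gave a higher p also for simulated genes that were independent, so its 0 calls do not by themselves show correlated genes.

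Without miR-302 replicate 1, which stood apart from the other miR-302 arrays, 5395 genes changed, 2484 higher and 2911 lower, and without any other single array the total lay between 1728 and 2077. Of the 3643 genes, 1561 also passed a fold change of 1.5, and an unmoderated test per gene called 480.

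**Figure D1:**
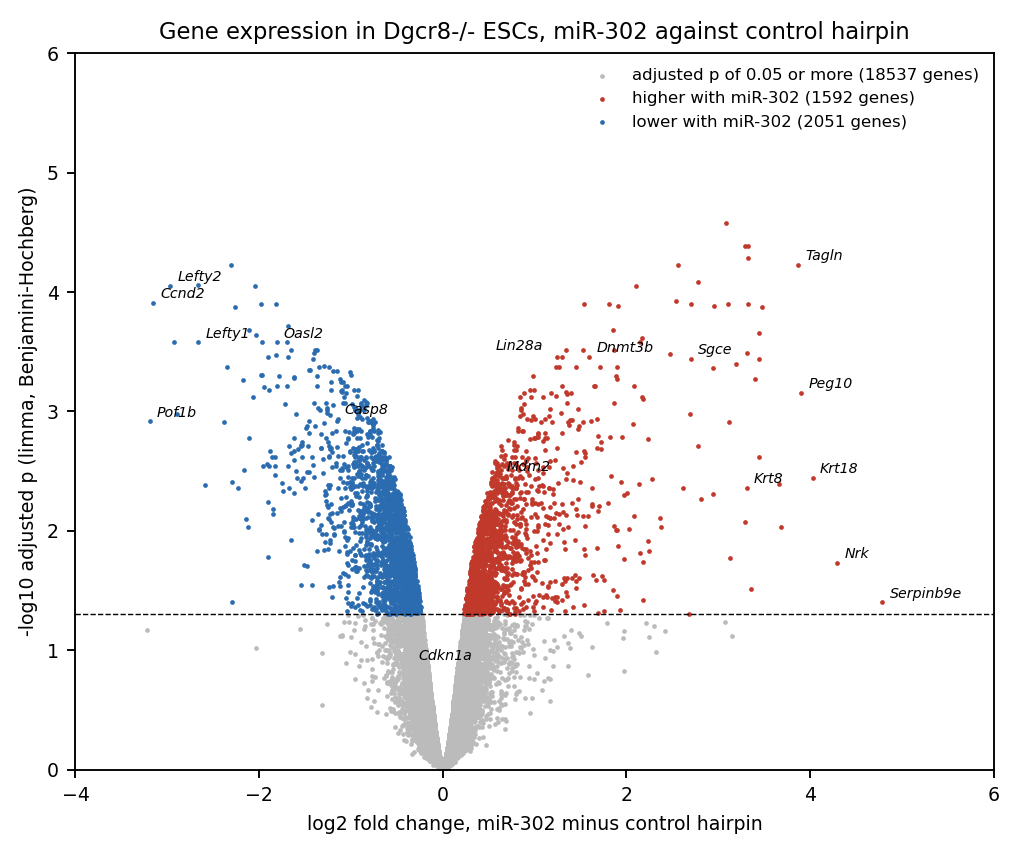
Each point is 1 of 22180 genes, with the log2 fold change of miR-302 over control hairpin on the x axis and −log10 of limma's adjusted p on the y axis (n = 3 per group). Red points (1592 genes) were higher and blue points (2051 genes) lower at an adjusted p under 0.05, the dashed line. Krt18 and Tagln lie far to the right, Ccnd2 and Lefty2 far to the left, and Cdkn1a below the line.

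Reported targets of the miR-302 family fell as a group. Of 24 measured genes, 11 were lower, 1 was higher and 12 were not called. Adjusted over the list alone, 12 were lower and 3 higher. The list's median log2 fold change was −0.29 (limma camera, adjusted p = 2.27e-05; adjusted p = 0.101 with an estimated correlation), with 3 higher and 13 lower without miR-302 replicate 1 and 0 higher and 7 to 9 lower without any 1 of the others. Ccnd2, which encodes cyclin D2, went from 11.42 ± 0.03 (SD, n = 3) in control cells to 8.26 ± 0.26 with miR-302, a log2 change of −3.16 ± 0.13 (SE), 8.92-fold lower (adjusted p = 0.000124). Lefty2 went from 10.85 ± 0.15 to 7.88 ± 0.16 and Lefty1 from 12.08 ± 0.10 to 9.42 ± 0.27, which is 7.82-fold and 6.33-fold lower. Casp8 fell from 7.44 ± 0.17 to 6.30 ± 0.04, a log2 change of −1.14 ± 0.10 (SE; adjusted p = 0.00115). Smaller falls were measured for Rbl2, a retinoblastoma family member (log2 change −0.76 ± 0.14 SE), and for the Hippo pathway kinase gene Lats2 (−0.33 ± 0.08 SE). In the 6 fits that left out 1 array, the call of Rbl2 was lost in 4 and that of Lats2 in 5. Dkk1, a secreted Wnt antagonist, was the called gene that was higher, by 1.14 on the log2 scale (adjusted p = 0.0356), a call lost without any 1 of the arrays other than miR-302 replicate 1. It lies outside the rule for named genes and was chosen after its value was seen. Cdkn1a, which encodes the cell cycle inhibitor p21, was 11.43 ± 0.06 in control cells and 11.09 ± 0.26 with miR-302 (adjusted p = 0.131), and Larp7 was 11.13 ± 0.06 and 11.03 ± 0.11 (adjusted p = 0.463). The difference of neither passed the test.

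Of 35 measured p53 target genes, 14 were higher, 3 lower and 18 not called. Adjusted over the list alone, 15 were higher and 3 lower. Among all 22180 genes tested, 1592 were higher and 2051 lower. With genes below the median level left out, 1815 of 11090 genes were higher and 2479 lower, and of 32 p53 target genes 13 were higher and 3 lower. For the 35 p53 target genes, the counts were 14 higher and 5 lower without miR-302 replicate 1 and 4 to 6 higher and 2 lower without any 1 of the others. With the replicate number as a block 6 of them were higher and 3 lower. Their median log2 fold change was 0.03 and their mean 0.11, and the list was not called against other genes (limma camera, adjusted p = 0.181; adjusted p = 0.415 with an estimated correlation). A test of whether its genes move 1 way on balance was past the threshold (fry, adjusted p = 0.00439, direction up). Mdm2, which encodes the ubiquitin ligase that limits p53, rose from 9.04 ± 0.06 to 9.66 ± 0.07 (SD, n = 3), 1.53-fold (adjusted p = 0.00345). The polo-like kinase genes Plk2 and Plk3 rose by 1.70 ± 0.16 and 1.53 ± 0.13 (SE) on the log2 scale. Ephx1, which encodes epoxide hydrolase, fell from 9.66 ± 0.07 to 8.14 ± 0.39, and Sesn2, a sestrin gene that is also in the stress list, fell from 9.95 ± 0.07 to 9.28 ± 0.14. The list's median was −0.03 without miR-302 replicate 1 and −0.02 without control hairpin replicate 2. Cdkn1a (above) is in this list and in that of the reported miR-302 family targets. It changed by −0.35 on the log2 scale and was not called (limma, adjusted p = 0.131). Trp53 itself was not analysed here.

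Most core pluripotency genes were not called. Of 14 measured, Lin28a was higher, Gdf3 was lower and 12 were not called, with the same counts adjusted over the list alone (median 0.05, adjusted p = 0.476; adjusted p = 0.910 with an estimated correlation). The call of Gdf3 was lost in 5 of the 6 fits that left out 1 array. Leaving out miR-302 replicate 1 gave 1 higher and 3 lower, and leaving out any 1 of the others 1 higher and 0 lower. Pou5f1 was 9.28 ± 0.05 in control cells and 9.32 ± 0.14 with miR-302, and Nanog 12.85 ± 0.03 and 12.74 ± 0.15. These 2 genes lie outside the rule for named genes and were chosen after their values were seen. Lin28a, which encodes an RNA-binding protein that blocks let-7 maturation, rose from 7.55 ± 0.08 to 8.79 ± 0.05 (2.37-fold, adjusted p = 0.000349). Sox2 was 12.01 ± 0.03 and 11.68 ± 0.20 (adjusted p = 0.0891), a difference that passed the test without miR-302 replicate 1. Of 17 naive pluripotency genes, 2 were higher, 2 lower and 13 not called, and 3 were higher and 2 lower adjusted over the list alone (median −0.16, adjusted p = 0.377; adjusted p = 0.835 with an estimated correlation). With miR-302 replicate 1 left out 2 higher and 6 lower were called, and with any 1 of the others left out 1 or 2 higher and 0 or 1 lower. Dppa3 rose by 1.31 ± 0.15 (SE) on the log2 scale. Klf2 changed by −0.82 ± 0.17 and lost its call in 5 of the 6 fits that left out 1 array. This list was called lower without miR-302 replicate 1 (adjusted p = 0.0185). Of 13 genes of the primed state, which follows implantation, 6 were higher, 3 lower and 4 not called, with the same counts adjusted over the list alone (median 0.19, adjusted p = 0.216; adjusted p = 0.522 with an estimated correlation). The counts were 7 higher and 4 lower without miR-302 replicate 1, and 2 to 5 higher and 2 or 3 lower without any 1 of the others. The DNA methyltransferase gene Dnmt3b rose from 9.08 ± 0.07 to 10.68 ± 0.15 (3.02-fold, adjusted p = 0.000349), whereas Zic2 and Zic5 changed by −1.03 ± 0.12 and −0.84 ± 0.09 (SE).

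**Figure D2:**
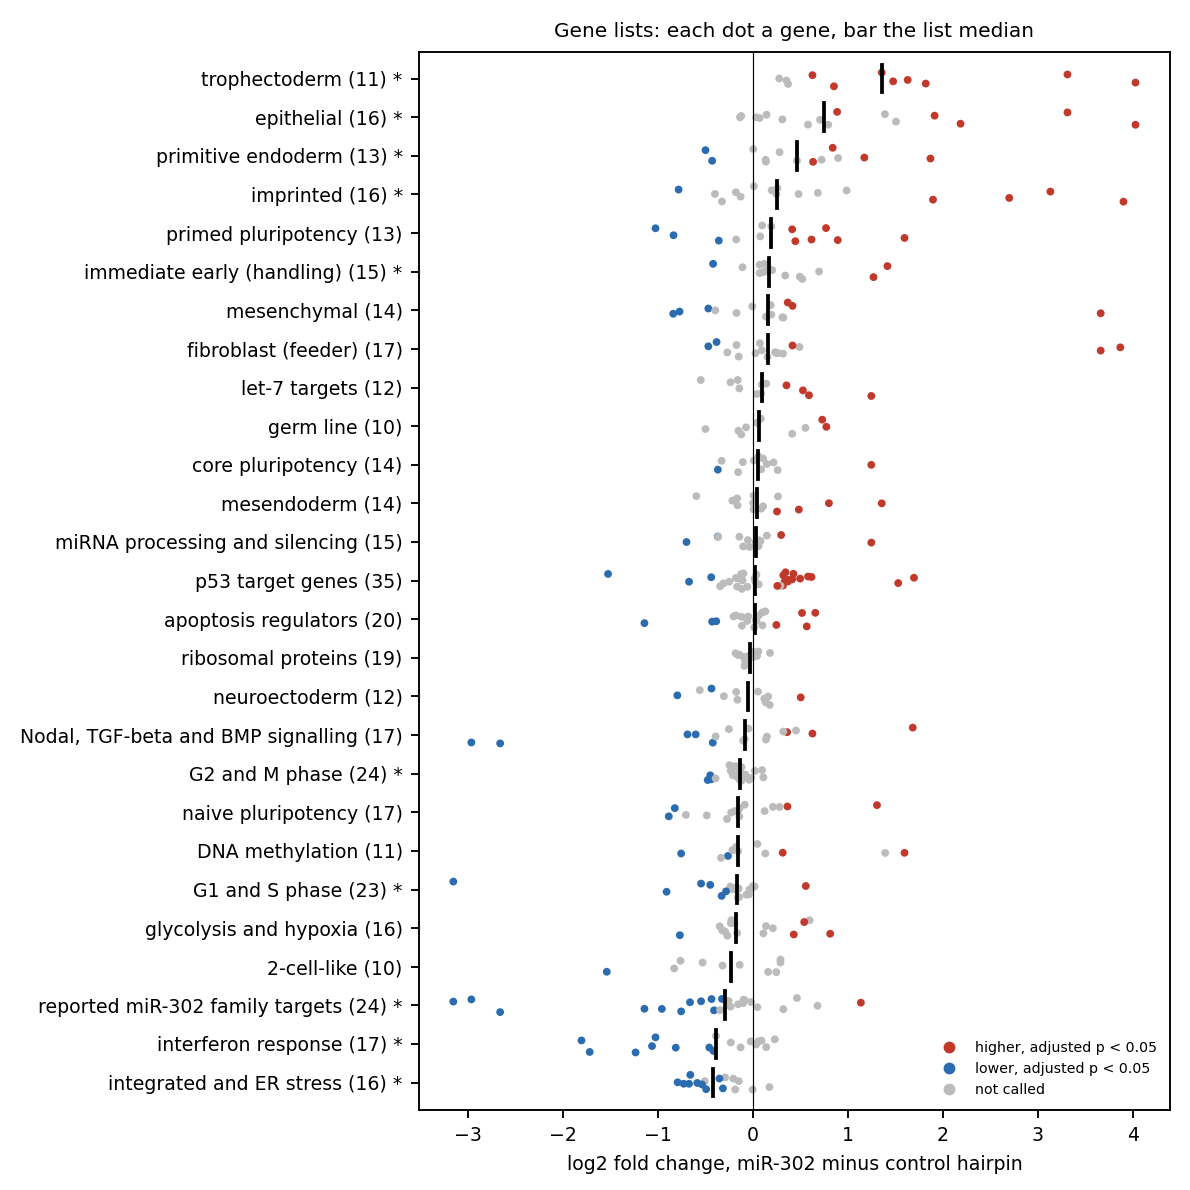
Each dot is 1 measured gene of a gene list, placed by its log2 fold change of miR-302 over control hairpin (x axis, log2 units), with lists on the y axis ordered by median and the number of measured genes in brackets. Black bars are list medians, red and blue dots are genes higher or lower at an adjusted p under 0.05, and an asterisk marks the 10 lists that limma camera called at a preset correlation of 0.01. The trophectoderm list has the highest median, 1.36, and the integrated and ER stress list the lowest, −0.42.

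Trophectoderm genes rose together. Of 11 measured, 8 were higher, none lower and 3 not called, and 9 were higher adjusted over the list alone (median 1.36, adjusted p = 9.93e-08; adjusted p = 0.211 with an estimated correlation). Krt18 rose from 7.09 ± 0.06 to 11.12 ± 1.09 (SD, n = 3), 16.3-fold (adjusted p = 0.00359), and Krt8 from 8.22 ± 0.11 to 11.54 ± 0.96, 9.94-fold (adjusted p = 0.00439). These keratins are also in the epithelial list. The transcription factor genes Ascl2, Gata3 and Eomes rose by 1.82 ± 0.17, 1.48 ± 0.12 and 1.36 ± 0.10 (SE). The large SD of the keratins came from miR-302 replicate 1, where Krt18 was 9.86 against 11.82 and 11.68 in replicates 2 and 3, and Krt8 10.43 against 12.07 and 12.11. The log2 change of Krt18 was 4.03, and 4.66 without that array. Without it 11 of the 11 trophectoderm genes were higher, and without any 1 of the others 7 or 8. Of the 11 genes, 8 lie at or above the median level, and with genes below that level left out all 8 were higher. A low level, such as that of Tpbpa (3.95 ± 0.11 and 4.23 ± 0.21), cannot be told from background.

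Epithelial genes were also higher as a list. Of 16, 5 were higher, none lower and 11 not called, and 6 were higher adjusted over the list alone (median 0.75, adjusted p = 0.000665; adjusted p = 0.639 with an estimated correlation). Beside the keratins, the tight junction gene Cldn6 and the polarity gene Crb3 rose by 1.91 ± 0.35 and 0.89 ± 0.19 (SE). Their calls were lost in 3 and 5 of the 6 fits that left out 1 array. Of the epithelial genes 13 were higher without miR-302 replicate 1, and 2 or 3 without any 1 of the others. Of 13 primitive endoderm genes, 4 were higher, 2 lower and 7 not called, and 6 were higher and 2 lower adjusted over the list alone (median 0.46, adjusted p = 0.0183; adjusted p = 0.233 with an estimated correlation), with 7 higher and 2 lower without miR-302 replicate 1 and 3 higher and 1 lower without any 1 of the others. The members that rose most were the laminin genes Lamb1 and Lama1, by 1.87 ± 0.10 and 1.17 ± 0.17 (SE), which encode basement membrane proteins that are not unique to this lineage. Pdgfra rose by 0.84 ± 0.14, and the endocytic receptor gene Cubn fell by 0.50 on the log2 scale. Of the lineage factor genes, Gata4 was lower (−0.43 ± 0.11 SE, adjusted p = 0.0375), against the list's rise, a call lost without any 1 of the arrays other than miR-302 replicate 1, and Gata6 and Sox17 were not called. These 3 genes lie outside the rule for named genes and were chosen after their values were seen. With only genes at or above the median level, the list was no longer called (adjusted p = 0.0540).

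Imprinted genes, expressed from 1 parental copy and sensitive to culture history, were higher as a list. Of 16, 4 were higher, 1 lower and 11 not called, and 7 were higher and 2 lower adjusted over the list alone (median 0.25, adjusted p = 0.0465; adjusted p = 0.712 with an estimated correlation). Leaving out miR-302 replicate 1 gave 8 higher and 2 lower, and leaving out any 1 of the others 2 higher and 1 lower. Peg10, a retrotransposon-derived gene needed for placenta formation, rose from 8.21 ± 0.05 to 12.11 ± 0.63 (15.0-fold, adjusted p = 0.000703), and its neighbour Sgce from 5.49 ± 0.31 to 8.19 ± 0.13 (6.50-fold). The growth factor gene Igf2 rose from 6.60 ± 0.12 to 9.73 ± 1.36 (adjusted p = 0.0168), with 8.16 in miR-302 replicate 1 and 10.48 and 10.56 in replicates 2 and 3. Its log2 change was 3.13, and 3.92 without that array, and its call was lost without any 1 of the other 5. Grb10, an adaptor gene that limits growth signalling, changed by −0.78 ± 0.10 (SE). The list's adjusted p was 0.000296 without miR-302 replicate 1, and the call was lost without control hairpin replicate 2 or 3 or miR-302 replicate 2 or 3, with adjusted p up to 0.151.

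Of 17 fibroblast genes, 3 were higher, 2 lower and 12 not called, with the same counts adjusted over the list alone (median 0.15, adjusted p = 0.181; adjusted p = 0.583 with an estimated correlation). With miR-302 replicate 1 left out 3 higher and 3 lower were called, and with any 1 of the others left out 2 or 3 higher and 1 lower. The smooth muscle genes Tagln and Acta2 rose by 3.87 ± 0.13 and 3.66 ± 0.46 (SE), or 14.6-fold and 12.7-fold (Acta2 by 4.25 without miR-302 replicate 1), while the fibronectin gene Fn1 changed by −0.47 ± 0.06. Of 14 mesenchymal genes, 3 were higher, 3 lower and 8 not called, and 4 were higher and 3 lower adjusted over the list alone (median 0.16, adjusted p = 0.562; adjusted p = 0.835 with an estimated correlation). The counts were 5 higher and 4 lower without miR-302 replicate 1, and 1 or 2 higher and 1 lower without any 1 of the others. Snai2 was higher by 0.37 ± 0.08 (SE) and the matrix metalloprotease gene Mmp2 changed by −0.84 ± 0.16. Each lost its call in 5 of the 6 fits that left out 1 array. Of 14 mesendoderm genes, 4 were higher, none lower and 10 not called, and 5 were higher adjusted over the list alone (median 0.05, adjusted p = 0.284; adjusted p = 0.583 with an estimated correlation), with 3 higher and 1 lower without miR-302 replicate 1 and 2 higher and 0 lower without any 1 of the others. With all arrays the higher genes beside Eomes were Wnt3, higher by 0.80 ± 0.10 (SE), Lhx1 and Foxa2, and the calls of Lhx1 and Foxa2 were lost without any 1 of the 6 arrays. Of 12 neuroectoderm genes, 1 was higher, 2 lower and 9 not called, and 1 was higher and 3 lower adjusted over the list alone (median −0.06, adjusted p = 0.562; adjusted p = 0.790 with an estimated correlation). Leaving out miR-302 replicate 1 gave 2 higher and 4 lower, and leaving out any 1 of the others 0 higher and 1 or 2 lower. Tubb3 and Sox1 changed by −0.44 ± 0.06 and −0.80 ± 0.14 (SE). The call of Sox1 was lost in 3 of the 6 fits that left out 1 array.

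**Figure D3:**
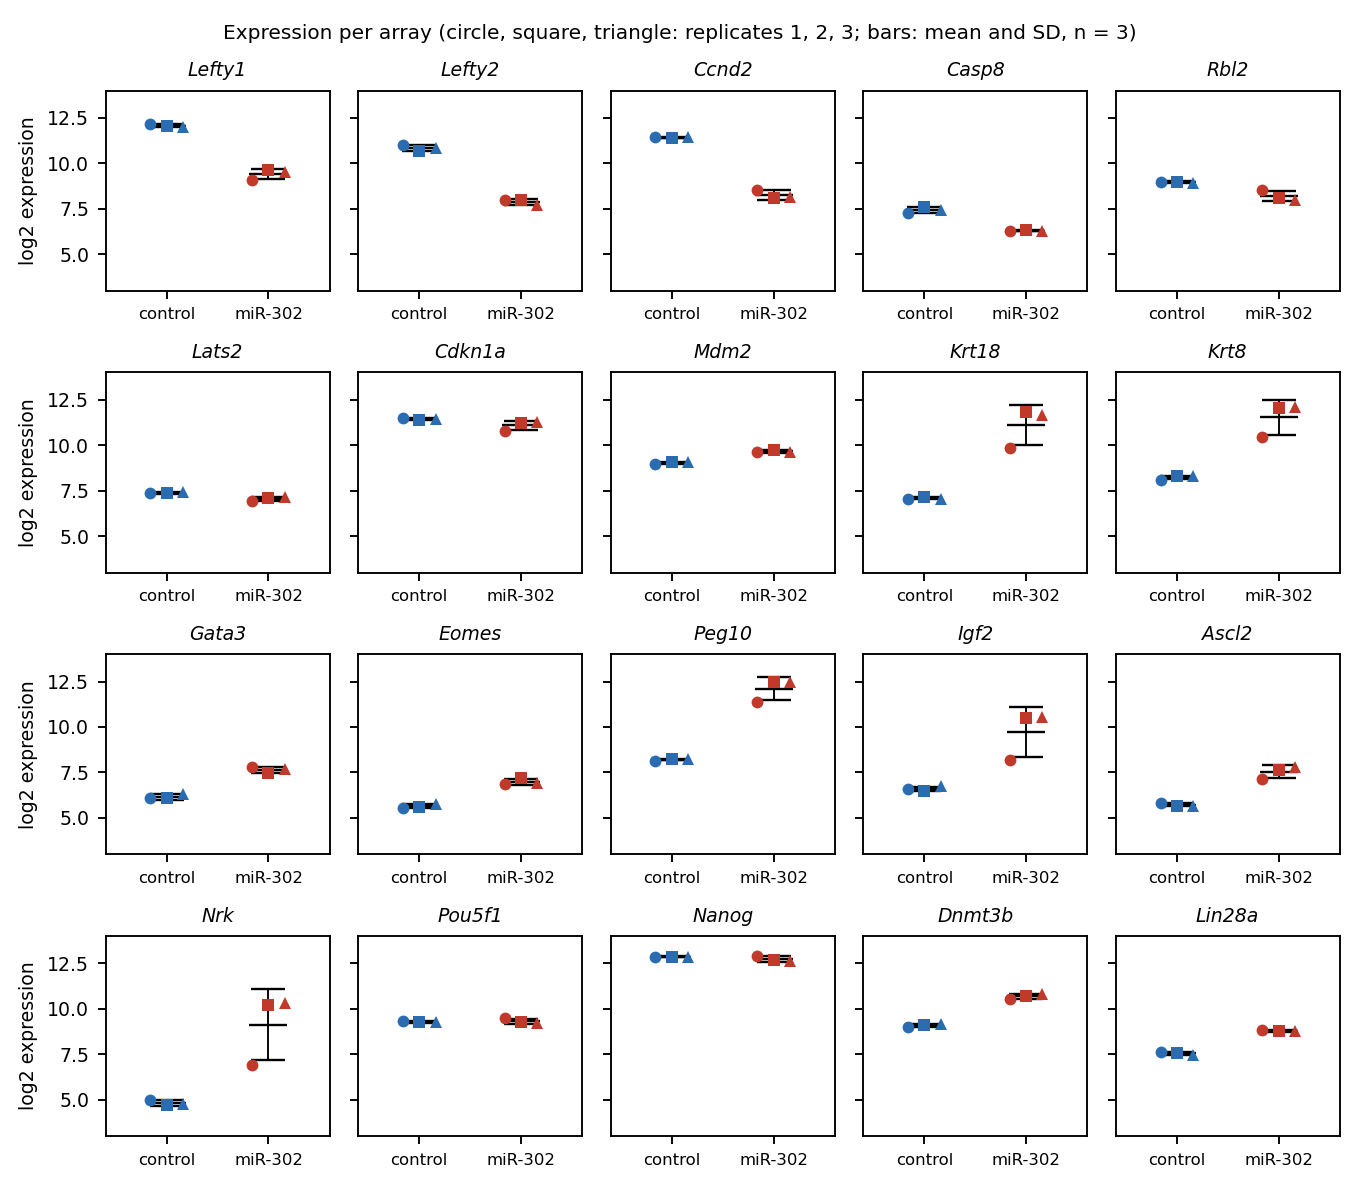
Each panel shows log2 expression (y axis) of 1 gene on the 3 control hairpin arrays (blue) and the 3 miR-302 arrays (red). Circles, squares and triangles are replicates 1, 2 and 3, and black bars are the mean and SD (n = 3). The 3 miR-302 arrays of Lefty2 and Ccnd2 lie together, while for Krt18, Krt8, Igf2 and Nrk the circle of replicate 1 lies between the control arrays and replicates 2 and 3.

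Genes of the G1 and S phases were lower as a list. Of 23, 6 were lower, 1 higher and 16 not called, and 7 were lower and 1 higher adjusted over the list alone (median −0.17, adjusted p = 0.000358; adjusted p = 0.101 with an estimated correlation). With miR-302 replicate 1 left out 1 higher and 8 lower were called, and with any 1 of the others left out 1 higher and 4 lower. The members that moved most were Ccnd2 (above) and E2f2 (−0.91 ± 0.10 SE). Of the other D-type cyclin genes, Ccnd1 was lower (−0.55 ± 0.07 SE) and Ccnd3 higher (0.56 ± 0.07 SE). Ccnd1 and Ccnd2 are also in the list of reported miR-302 family targets. Of 24 genes of the G2 and M phases, 3 were lower (Ccnb2, Nusap1 and Bub1b, with log2 changes from −0.48 to −0.44), none higher and 21 not called, with the same counts adjusted over the list alone (median −0.14, adjusted p = 0.00207; adjusted p = 0.522 with an estimated correlation). The counts were 0 higher and 5 lower without miR-302 replicate 1, and 0 higher and 1 or 2 lower without any 1 of the others. An intensity trend with a robust prior called 11 lower in the list of the G1 and S phases and 10 in this one, and with genes below the median level left out 10 and 9 were lower. Of 20 apoptosis regulators, 4 were higher, 3 lower and 13 not called, with the same counts adjusted over the list alone (median 0.02, mean −0.01, direction up in camera, adjusted p = 0.862; adjusted p = 0.910 with an estimated correlation), with 4 higher and 3 lower without miR-302 replicate 1 and 1 to 3 higher and 1 or 2 lower without any 1 of the others. The anti-apoptotic genes Bcl2l1 and Bcl2 rose by 0.52 ± 0.08 and 0.57 ± 0.11 (SE), the pro-apoptotic gene Bcl2l11 rose by 0.66 ± 0.12, and Casp8 fell. The calls of Bcl2, Bcl2l11, Nusap1 and Bub1b were lost in 4, 3, 3 and 5 of the 6 fits that left out 1 array.

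Stress response genes were lower as a list at the preset correlation. Of 16 integrated and ER stress genes, 9 were lower, none higher and 7 not called, and 12 were lower adjusted over the list alone (median −0.42, adjusted p = 4.32e-06; adjusted p = 0.101 with an estimated correlation). The counts were 1 higher and 10 lower without miR-302 replicate 1, and 0 higher and 5 or 6 lower without any 1 of the others. Xbp1, a transcription factor gene of the unfolded protein response, changed by −0.66 ± 0.07 (SE), the ER protein gene Sdf2l1 by −0.79 ± 0.11 and the serine synthesis gene Psat1 by −0.54 ± 0.07. Of 17 interferon response genes, 8 were lower, none higher and 9 not called, with the same counts adjusted over the list alone (median −0.39, adjusted p = 0.000665; adjusted p = 0.101 with an estimated correlation). The oligoadenylate synthetase-like genes Oasl2 and Oasl1 changed by −1.81 ± 0.10 and −1.72 ± 0.13 (SE), 3.50-fold and 3.29-fold lower, and Rsad2 and Irf9 by −1.06 ± 0.08 and −1.03 ± 0.12. Oasl2 went from 7.81 ± 0.06 to 6.01 ± 0.16 (SD, n = 3; adjusted p = 0.000264).

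Genes of Nodal, TGF-beta and BMP signalling moved in both directions. Of 17, 3 were higher, 5 lower and 9 not called, and 5 were higher and 5 lower adjusted over the list alone (median −0.09, adjusted p = 0.468; adjusted p = 0.639 with an estimated correlation). Beside Lefty1 and Lefty2, the activin receptor gene Acvr1b changed by −0.60 ± 0.07 (SE), and Id2, which encodes an inhibitor of helix-loop-helix factors, rose by 1.68 ± 0.17. Of 15 miRNA processing and silencing genes, 2 were higher, 2 lower and 11 not called, and 2 were higher and 3 lower adjusted over the list alone (median 0.03, adjusted p = 0.910 with either correlation). Leaving out miR-302 replicate 1 gave 2 higher and 3 lower, and leaving out any 1 of the others 1 higher and 1 lower. Tnrc6a, a partner of Argonaute proteins, changed by −0.70 ± 0.09 (SE). The knocked-out gene Dgcr8 is measured only on a row annotated to it and to Mir1306, which read 8.25 ± 0.05 in control cells and 8.04 ± 0.06 with miR-302 (adjusted p over rows = 0.148). As both groups lack the gene and the position of the deletion against the probes is not used here, this row checks no label.

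Of 11 DNA methylation genes, 2 were higher, 2 lower and 7 not called, and 3 were higher and 3 lower adjusted over the list alone (median −0.16, mean 0.14, direction down in camera and up in fry, adjusted p = 0.905; adjusted p = 0.910 with an estimated correlation). With miR-302 replicate 1 left out 3 higher and 6 lower were called, and with any 1 of the others left out 1 higher and 0 or 1 lower. Dnmt3b rose as given above. Dnmt1, the maintenance methyltransferase gene, changed by −0.26 ± 0.06 (SE) and lost its call in 5 of the 6 fits that left out 1 array. Of 16 glycolysis and hypoxia genes, 3 were higher, 1 lower and 12 not called, with the same counts adjusted over the list alone (median −0.18, mean 0.0006, direction down in camera and up in fry, adjusted p = 0.811; adjusted p = 0.910 with an estimated correlation). The counts were 3 higher and 5 lower without miR-302 replicate 1, and 1 to 4 higher and 0 lower without any 1 of the others. The glucose transporter genes Slc2a1 and Slc2a3 rose by 0.54 ± 0.07 and 0.43 ± 0.08 (SE), and Slc2a3 lost its call without 1 of the arrays. Of 12 reported let-7 targets, 4 were higher, none lower and 8 not called, and 4 were higher and 2 lower adjusted over the list alone (median 0.09, adjusted p = 0.200; adjusted p = 0.522 with an estimated correlation), with 4 higher and 1 lower without miR-302 replicate 1 and 2 higher and 0 lower without any 1 of the others. With all arrays the higher genes were Lin28a, E2f6 (0.59 ± 0.09 SE), Nras and Igdcc3. Nras and Igdcc3 each lost their call in 5 of the 6 fits that left out 1 array.

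Of 10 germ line genes, Taf7l and Ddx4 were higher, by 0.77 ± 0.20 and 0.73 ± 0.20 (SE), none was lower and 8 were not called, with the same counts adjusted over the list alone (median 0.06, adjusted p = 0.562; adjusted p = 0.910 with an estimated correlation). Leaving out miR-302 replicate 1 gave 2 higher and 2 lower, and leaving out any 1 of the others 0 or 1 higher and 0 lower. Of 10 genes of the 2-cell-like state, 1 was lower, none higher and 9 not called, with the same counts adjusted over the list alone (median −0.23, adjusted p = 0.520; adjusted p = 0.902 with an estimated correlation). With miR-302 replicate 1 left out 0 higher and 4 lower were called, and with any 1 of the others left out 0 higher and 0 lower. With all arrays the lower gene was Zscan4c, at 6.76 ± 0.17 and 5.22 ± 0.76, a member of a family of near-identical copies that share array signal. The calls of Zscan4c, Taf7l and Ddx4 were lost without some single arrays. Of 19 ribosomal protein genes, a sign of RNA quality, none was called in the fit used here (0 higher and 0 lower by limma, over all genes or adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by the unmoderated test, but 1 lower by limma with an intensity trend and a robust prior; median −0.03, adjusted p = 0.476; adjusted p = 0.835 with an estimated correlation). Of 15 immediate early genes, which respond to handling, 2 were higher, 1 lower and 12 not called, with the same counts adjusted over the list alone (median 0.17, adjusted p = 0.0465; adjusted p = 0.583 with an estimated correlation). The counts were 7 higher and 1 lower without miR-302 replicate 1, and 2 higher and 0 or 1 lower without any 1 of the others. Myc and Zfp36 rose by 1.42 ± 0.17 and 1.27 ± 0.20 (SE), and Egr1 changed by −0.42 ± 0.10, a call lost without some single arrays. This list's adjusted p was 0.000296 without miR-302 replicate 1, and the call was lost without control hairpin replicate 2 or 3 or miR-302 replicate 2 or 3, with adjusted p up to 0.152.

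Serpinb9e, a protease inhibitor gene with near-identical copies, was higher by 4.79 ± 1.21 (SE) on the log2 scale (adjusted p = 0.0397), but the size of this rise is uncertain. The control arrays read 3.76 to 4.15, below the lower quartile of each array (4.23 to 4.27), and the miR-302 arrays 5.65, 10.37 and 10.34, so the log2 change was 6.36 without miR-302 replicate 1 and about 4 without replicate 2 or 3. Nrk, an X-linked kinase gene expressed in placenta, rose from 4.83 ± 0.16 to 9.13 ± 1.94, and Nxf7 from 5.07 ± 0.15 to 8.43 ± 1.76. These log2 changes of 4.30 and 3.36 became 5.42 and 4.37 without miR-302 replicate 1. The calls of Serpinb9e, Nrk and Nxf7 held without miR-302 replicate 1 and were lost without any 1 of the other 5 arrays. Thbs1, Anxa2 and Foxi3 rose by 3.68 ± 0.60, 3.45 ± 0.17 and 3.40 ± 0.23 (SE; Thbs1 by 4.46 without miR-302 replicate 1), and the miRNA gene rows Mir669g and Mir466n by 3.48 ± 0.16 and 3.45 ± 0.21. Among the largest falls were Pof1b, an actin-binding protein gene, from 8.25 ± 0.12 to 5.06 ± 0.60 (9.15-fold lower), the protocadherin gene Fat2 by 2.89 on the log2 scale, and Igfbp7 from 10.83 ± 0.07 to 8.17 ± 0.16 (6.33-fold lower). Tgfbi, Tspo2, Lgals3bp, Cpe and Zscan4b followed, with log2 changes from −2.59 to −2.30, and Zscan4b, another near-identical copy, changed by −3.03 without miR-302 replicate 1 and lost its call without any 1 of the others. The Mirlet7c-2 row went from 7.04 ± 0.31 to 4.12 ± 0.10 (adjusted p = 0.000264).

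The rows of the endogenous miR-302 cluster genes were low in both groups. Mir302b was 4.30 ± 0.14 in control cells and 5.21 ± 0.55 with miR-302 (adjusted p = 0.0585), and the adjusted p of Mir302a, Mir302c and Mir302d were 0.116, 0.213 and 0.175. Without miR-302 replicate 1, Mir302a, Mir302b and Mir302c were called higher, with an adjusted p of 0.00107 for Mir302b. Whether these rows detect the introduced hairpin is not known here. Mir290a, of the related miR-290 cluster, was 12.47 ± 0.06 and 12.51 ± 0.03 (adjusted p = 0.755).

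The arrays of each group lay closer to each other than to the other group. Correlations across genes, which are not independent replicates, were 0.9961 to 0.9966 among the control hairpin arrays and 0.9965 between miR-302 replicates 2 and 3. miR-302 replicate 1 correlated with replicates 2 and 3 at 0.9901 to 0.9902 and with the control arrays at 0.9862 to 0.9870, against 0.9814 to 0.9830 for replicates 2 and 3 with the control arrays. The control and miR-302 arrays did not overlap for 7934 genes (35.8%), where chance gives 10%.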

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

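The tests of miR-302 replicate 1 and of other cell types, except that of differentiated trophoblast, were chosen after the result was seen. Rows outside the gene-level comparison also moved, but a smaller share of them than of the 22180 genes (1592 higher and 2051 lower). Of 1814 rows annotated to several genes, 79 were higher with miR-302 and 78 lower. Of 8314 rows without a listed gene, 183 were higher and 230 lower. Without miR-302 replicate 1 these counts were 115 and 133 for rows of several genes and 236 and 303 for rows without a gene, and without any 1 of the other arrays 46 to 53 and 40 to 66, and 86 to 106 and 86 to 142.

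The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3643 genes and the highest other split 0, and 1 of the 10 splits gave as many genes. Each other split joins 2 arrays of 1 group with 1 of the other. The miR-302 difference then widens the spread within each side, so few calls are built in and the gene counts decide nothing. For gene lists, the real split called 10 and the highest other split also 10, so that 2 of the 10 splits gave as many. The splits that put miR-302 replicate 1 with 2 control arrays called 9, 9 and 10 lists, and those with replicate 2 or 3 in its place 0 to 4. All of these splits keep part of the miR-302 difference. The higher counts came with replicate 1, which lies at a distance from replicates 2 and 3.

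miR-302 replicate 1 differed from the mean of replicates 2 and 3 by over 1 log2 unit for 303 genes, against at most 20 for a control array. Control cells or RNA mixed into it would act on linear levels. All genes would then lie the same share of the way from control to replicates 2 and 3. Instead, that share had a median of 83.6% for 98 genes that fell and 33.3% for 178 that rose, a gap of 50.3 percentage points. A linear share is smaller than a log2 share for rises and larger for falls. The gap therefore does not show that falls were nearer completion. Krt18, with a linear share of 23.9%, read 9.86 in replicate 1, against 7.09 in controls and 11.75 in replicates 2 and 3. Lefty2 was 7.98 in replicate 1, where a mixture at the share of the risen genes gives 10.36. A difference of the whole array in intensity would move genes of like level alike. In 10 groups of genes by control level, the median difference lay between −0.01 and 0.035, and genes over 1 log2 unit away lay on both sides in each group, 98 above and 205 below in all. The rarer direction of each group summed to 96 genes, against at most 5 for a control array. This argues against a difference by level that was left after RMA. RMA makes the arrays alike beforehand, so the medians near 0 decide nothing. An effect of RNA quality that moves genes of like level both ways was not tested. A different culture state or time of miR-302 expression stays open and was not tested.

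Genes of the trophectoderm list, and the smooth muscle genes Acta2 and Tagln, were higher with miR-302. Differentiated placental trophoblast cannot be told apart from a rise of trophectoderm genes in ESCs. The median log2 fold change of its list of 24 measured genes was 0.12 against 1.36 for trophectoderm, under the bound set before this value was seen, but that bound took no account of level, by which the list was split afterwards: 20 of the 24, most of them prolactin, Psg and cathepsin genes, lie below the median level of 6.16 in both groups, where a value near 0 decides nothing, and the other 4 ranged from −0.10 to 2.15 with a median of 0.52. Plac1 was the called member, a call lost without any 1 control hairpin array or miR-302 replicate 2. Without miR-302 replicate 1, 5 members were higher and 1 lower. A subpopulation of trophoblast-like cells cannot be told apart from a rise in all cells: core pluripotency genes had a median of 0.05, and a small share of cells with high keratin levels would leave them there. Feeder fibroblasts as the source of Acta2 and Tagln are argued against by the other 15 fibroblast genes, whose median was 0.093 (quartiles −0.16 and 0.26) against at least 3.66. The 7 of them at or above the median level ranged from −0.47 to 0.49.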

How the results depend on the processing

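Of the 101 named genes that were called, 64 were called in every fit that left out 1 array, and no named gene changed sign in the settings where it was tested. Of the 122 named genes, 101 lie at or above the median level and were tested with the other genes left out. With the replicate number as a block, 2293 genes changed (964 higher, 1329 lower), 79 of the 101 named genes kept their call, and all 10 called lists were called. Arrays with the same number did not deviate together (correlations 0.019, 0.017 and 0.008), and 3 of the 6 arrays correlated best with the array of their own number in the other group, so the numbers are not taken as pairs. With 1 array left out, 1728 to 5395 genes changed, 685 to 2484 higher and 1043 to 2911 lower. The highest counts are those without miR-302 replicate 1. The lowest, with each of the other 5 arrays left out, come from fits that keep miR-302 replicate 1. Every fit without 1 array has the same number of arrays, so sample number does not separate the highest counts from the lowest. Array weights, which gave miR-302 replicate 1 a weight of 0.285 against at least 1.15 for the others, called 5621 genes (2617 higher, 3004 lower). The unmoderated test called 480 (200 higher, 280 lower), and it also recovered fewer genes in simulated data, 12.5% of 2-fold changes against 75%. A fold change of at least 1.5 left 1561 (636 higher, 925 lower), by construction. The trend with a robust prior gave 4591, median centring 3599, quantile normalization 3589, the mean of rows 3579 and every row on its own 3599. With genes below the median level left out, 4294 of 11090 genes changed, 2964 of them among the 3643. Of the 10 called lists, 8 were called in every fit that left out 1 array. The immediate early and imprinted lists lost their call in 4 of these fits each and with genes below the median level left out, as did primitive endoderm in the latter. Within lists, the trend with a robust prior called 11 G1 and S, 10 G2 and M, 6 naive, 6 glycolysis and hypoxia, 4 DNA methylation and 3 let-7 target genes lower and 7 imprinted genes higher. Array weights called 11 epithelial, 8 imprinted and 7 primitive endoderm genes higher and 8 glycolysis and hypoxia genes lower. With an estimated correlation 0 lists were called. The reported miR-302 targets (median −0.29) then had an adjusted p of 0.101. The p53 list (median 0.027) was called by fry (adjusted p = 0.00439), and its median was −0.022 with genes below the median level left out and lay between −0.03 and 0.068 without 1 array. Medians near 0 of other lists that were not called also changed sign without 1 array: core pluripotency lay between −0.017 and 0.099, mesendoderm between −0.005 and 0.097, neuroectoderm between −0.118 and 0.028, germ line between −0.068 and 0.332, apoptosis regulators between −0.017 and 0.028, and miRNA processing between −0.0083 and 0.03. With genes below the median level left out, miRNA processing was at −0.0033. The cause of the other differences was not tested. Seed matches of miR-302 were not run. The 2-cell-like list had too few genes at or above the median level to be tested there. Signal over background limits the dim genes, for which no detection call was used.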

Other observations

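The lists of SRF and of YAP and TEAD targets were set up after the data were examined, with genes already seen left out, and the tests of the miRNA rows were chosen after their values were seen. Genes of the actin cytoskeleton were higher with miR-302. Of 21 targets of the serum response factor SRF, 12 were higher and none lower, and 13 were higher adjusted over the list alone. Without 1 array, 9 to 15 were higher and none lower. The calponin genes Cnn1 and Cnn2 rose by 2.28 ± 0.28 and 2.17 ± 0.11 (SE) on the log2 scale, the tropomyosin genes Tpm1, Tpm2 and Tpm4 by 0.93 to 1.35, and Fhl2 by 1.87. Actb was 11.08 ± 0.11 and 11.44 ± 0.15 (adjusted p = 0.0554) and Srf itself was not called. Without miR-302 replicate 2 Actb was called higher, and without miR-302 replicate 1 Srf was called. A hypothesis is that SRF-responsive genes rose in general, and the list's median of 0.59 goes with it (camera, adjusted p = 6.22e-10, and 0.155 with an estimated correlation). This is no independent test: the list was tested on the same arrays whose values prompted it. Its genes also moved together, with an estimated correlation of 0.42. Of 21 targets of YAP and TEAD, the effectors of the Hippo pathway in which Lats2 acts, 8 were higher, among them Ccn1 (1.80) and Ptpn14 (0.84), and Nuak2 was lower (−0.49). Of these targets 12 were higher without miR-302 replicate 1, and 2 or 3 without any 1 of the others, with Nuak2 lower in each. In replicate 1 several of the rises were smaller: Ccn1 read 9.52 there against 10.34 and 10.53 in replicates 2 and 3, and F3 8.86 against 10.21 and 10.33, while Ptpn14 read 10.23 against 10.21 and 10.25. The median of the YAP and TEAD list was 0.33 (camera, adjusted p = 0.000965, and 0.155 with an estimated correlation). That goes with a rise of YAP and TEAD targets but is no independent test either. SRF and YAP targets overlap in their biology, and these data do not separate them.

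miRNA genes of the Mir297, Mir466, Mir467 and Mir669 families were higher with miR-302. In the annotation 22 of their rows lie inside Sfmbt2, an imprinted Polycomb-related gene of the trophoblast lineage, and 21 of these were higher, with Mir466h not called. Sfmbt2 itself rose from 5.05 ± 0.18 to 8.15 ± 0.20 (8.59-fold), and the median of the 22 rows was 2.70, against −0.01 for 459 rows of other miRNA genes, of which 12 were higher and 32 lower. Without 1 array, 19 to 21 of the 22 rows were higher, and of the 459 rows 24 were higher and 40 lower without miR-302 replicate 1, and 3 to 8 higher and 13 to 24 lower without any 1 of the others. A candidate explanation is transcription through Sfmbt2, since Dgcr8-deficient cells do not process primary transcripts. Signal shared between near-identical copies cannot be told apart from it by the same families outside Sfmbt2, as these are only Mir466i and Mir467f (median −0.065, neither called).

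Rows of let-7 genes moved apart. Mirlet7c-2 and Mirlet7b, which neighbour each other, were lower, with log2 changes of −2.93 and −1.18, Mirlet7e was higher by 0.44 (a call lost without any 1 of the arrays other than miR-302 replicate 1), and the other 8 let-7 rows were not called. Without miR-302 replicate 1, 2 of the 11 rows were higher and 3 lower. On 2 rows annotated to 6 Zscan4 genes, controls read 7.50 ± 0.11 and 8.48 ± 0.03. miR-302 replicate 1 read 6.67 and 7.71, and replicates 2 and 3 read 3.99 and 4.12 on the first and 4.43 and 4.42 on the second (adjusted p over rows = 0.0565 and 0.0730).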
